A study of Homo sapiens with 8 samples.

How the data were processed

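Hi-C was performed in U2OS cells under 4 conditions with 2 biological replicates each, 8 samples in all, per the labels. Samples were grouped by the siRNA and the treatment in their titles. The reads were processed by the submitters with Trimmomatic 0.36, BWA and Juicer on the genome build hg19, per the submitters' processing notes, which state neither the order nor the role of these tools. The TAD caller, its settings, the restriction enzyme, the number of contacts per map and whether the replicates were pooled are not given in the sources used here. The deposited files are 4 TAD lists, 1 per condition, whose values are genomic positions in bases: the start and end of each TAD, with no score and no count. All positions (100%) were multiples of 40 kb, which was taken as the bin of the contact maps. Starts are printed counted from 1.

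Because a list gives only which domains passed a caller, a change in the number of contacts or in the caller's settings between conditions would change the list in the same way as a change in folding. The depth of each map is unknown, and no interval given here covers it or the spread between cultures.

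A boundary was defined as a distinct start or end of a TAD in a list, and it counted as found in another list if that list had a boundary within 1 bin. The share found was given in both directions for each of 4 comparisons, with a 95% Wilson interval, and beside it the mean and range of the share after 200 random circular shifts of the other list within the span that the TADs cover on each chromosome. TADs were put in the first class that held: kept (both edges within 1 bin), merged (inside a larger TAD that holds at least 2 TADs of the first list), split (holding at least 2 TADs of the other list), without a TAD (under 50% of the length covered by the other list) or shifted. Medians and means of TAD size were given with a bootstrap interval over TADs from 1000 draws. Numbers of TADs were compared over the genome and by chromosome, with no p-value, since TADs and chromosomes are not replicates. To follow boundaries across all 4 lists, boundaries that lay within 1 bin of each other were joined into sites, and 98.3% of the sites were at most 1 bin wide.

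The regions named were chosen by a rule: in each comparison the 5 regions with the longest run of consecutive boundaries of the reference list without a match in the other list, with ties broken by span and then by position. The comparisons, definitions, naming rule and most alternatives were fixed before the data were examined. The alternatives covered the match tolerance, the definition of a kept TAD, filters on TAD size, the chromosomes used, boundaries near long stretches without TADs, and random thinning of the longer list to the length of the shorter. A few more were added after the data were seen.

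The classification of TADs was tested on simulated data made from 5187 TADs of the control list, after leaving out 242 that overlapped an earlier TAD in part. Of these TADs, 200 were removed, 200 merged, 200 split and 200 shifted at their start. All 200 of each kind and all 4387 kept TADs were recovered. The changes were made to match the class definitions, with no noise at other edges, so this checks the code and not how the classes perform on real lists. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

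An hg19 genome and gene annotation were not used here, so TADs around genes of 10 lists fixed in advance, and the sequence and genes at missing boundaries, were not analysed, and regions are named by coordinates only. The gene table at hand was of assembly GRCh38.p14, and coordinates were not converted between builds.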

Results

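Chromosome folding was measured by Hi-C in U2OS cells, an established human osteosarcoma cell line. Hi-C crosslinks chromatin, cuts and religates the DNA, and counts by sequencing which genomic fragments lay close together. From such contact maps topologically associating domains (TADs) are called, stretches of a chromosome that contact themselves more than their surroundings, and their edges are called boundaries. The 8 samples formed 4 groups of 2 biological replicates. Cells received a control siRNA or an siRNA against NAT10, an acetyltransferase best known for its nucleolar and RNA-modifying roles, and each of these was left untreated or given β-hydroxybutyrate (BHB), a ketone body that circulates during fasting. The deposited data analysed here were 4 TAD lists, 1 per condition, with the chromosome, start and end of each TAD in hg19 coordinates. No list was separated by replicate and none carried contact counts, so the depth of the maps is unknown, the spread between replicates could not be measured, and no p-value was computed between conditions. Intervals given for shares are 95% Wilson intervals, which cover counting error only and treat boundaries as independent. The lists hold no measure of NAT10 itself, so the knockdown was not checked here.

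All 4 lists covered chromosomes 1 to 22 and X, and no TAD lay inside another. The control cells had 5429 TADs with 7893 distinct boundaries, the BHB-treated control cells 3655 TADs with 5732 boundaries, the NAT10-knockdown cells 5215 TADs with 7658 boundaries, and the BHB-treated knockdown cells 5391 TADs with 7825 boundaries. The median TAD size was 280 kb in each of the 4 lists, and the bootstrap interval over TADs was 280 to 280 kb in each. Sizes come in steps of 40 kb, so this interval cannot show smaller differences. The first quartile was 200 kb in control cells and 240 kb in the other lists. The mean was 288.9 kb (283.5 to 295.7) in control cells and 300.1 kb (292.1 to 309.3) in BHB-treated control cells. It was 294.6 kb (288.6 to 301.5) in knockdown cells and 300.7 kb (291.8 to 312.1) in BHB-treated knockdown cells. The last mean includes a TAD of 21.4 Mb that no other list had, and means without the largest TADs were not computed. TADs covered 1558.2 Mb in control cells, 1093.8 Mb in BHB-treated control cells, 1528.0 Mb in knockdown cells and 1612.1 Mb in BHB-treated knockdown cells.

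**Figure D1:**
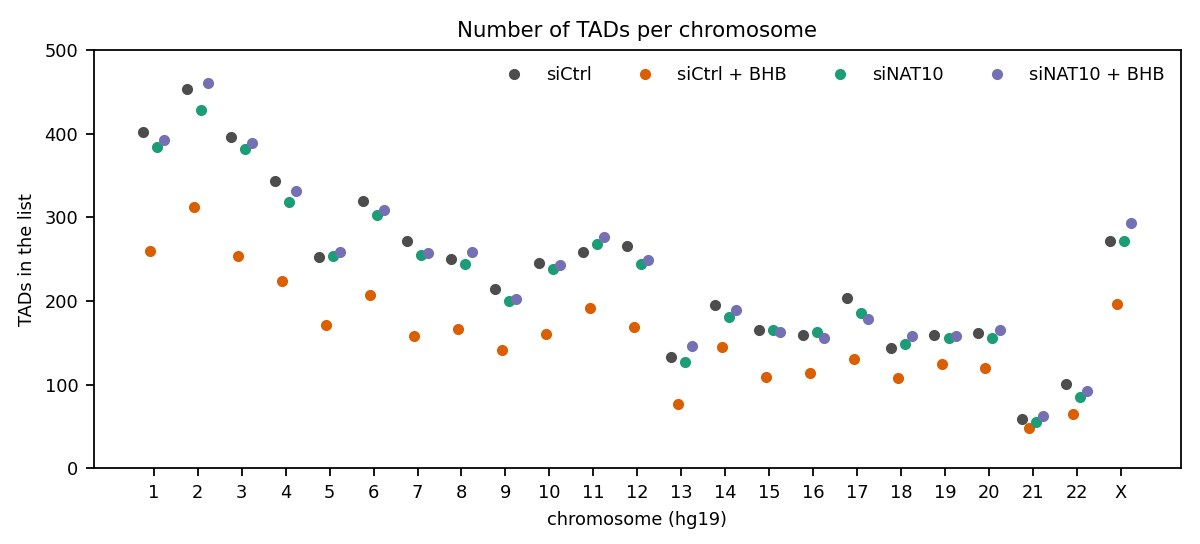
Number of TADs (vertical axis) on each chromosome of hg19 (horizontal axis) in the 4 deposited lists, 1 point per list. The BHB-treated control list (orange) is the lowest of the 4 on all 23 chromosomes, as on chromosome 13 with 77 TADs against 133 in control cells.

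The first comparison asked what BHB did to TADs in cells with NAT10. The BHB-treated control list had 32.7% fewer TADs than the untreated control list, and it had fewer on all 23 chromosomes. As a percentage of the control number, the difference was widest on chromosome 13, with 77 TADs against 133, and on chromosome 7, with 158 against 272. By the same measure it was narrowest on chromosome 21, with 48 against 59, and on chromosome 19, with 125 against 160. The genome covered by TADs was 464.4 Mb smaller and was lower on 22 chromosomes. On chromosome 21 it was 17.1 Mb against 16.6 Mb, and there the BHB-treated list alone of the pair had a TAD of 3.68 Mb, from 10960001 to 14640000. Whether that TAD lies over a gap in the hg19 sequence was not checked. Stretches of over 1 Mb without any TAD numbered 473 with BHB and 310 without.

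Of the 7893 boundaries in control cells, 5478 had a boundary within 1 bin of 40 kb in the BHB-treated list, a share of 69.4% (68.4 to 70.4), and 2415 did not. When the TADs of the BHB-treated list were shifted around each chromosome at random, the share found was 23.6% on average (22.0 to 25.3 over 200 shifts). In the other direction 93.7% (93.0 to 94.3) of the 5732 boundaries of the BHB-treated list were found in control cells, with 32.1% under random shifts, and 363 were not. With the control list thinned at random to 3655 TADs, 1508 (26.3%) of the boundaries of the BHB-treated list were not found. Of the thinned control list's boundaries, 28.6% were not found in the treated list. Random removal of TADs takes matches away by itself, so a rise from 363 was fixed in advance. It does not show whether the treated list is close to a part of the control list. At exactly the same position in the full control list, 1031 boundaries of the BHB-treated list were not found. Of the control TADs, 3157 (58.2%) kept both edges with BHB. A further 1867 (34.4%, interval 33.1 to 35.7) had under 50% of their length covered by any TAD of the treated list, while 77 lay within a merged TAD, 30 were split and 298 were shifted. The share without a TAD was 43.6% on chromosome 13 and 43.0% on chromosome 7, against 23.8% on chromosome 19 and 22.0% on chromosome 21.

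**Figure D2:**
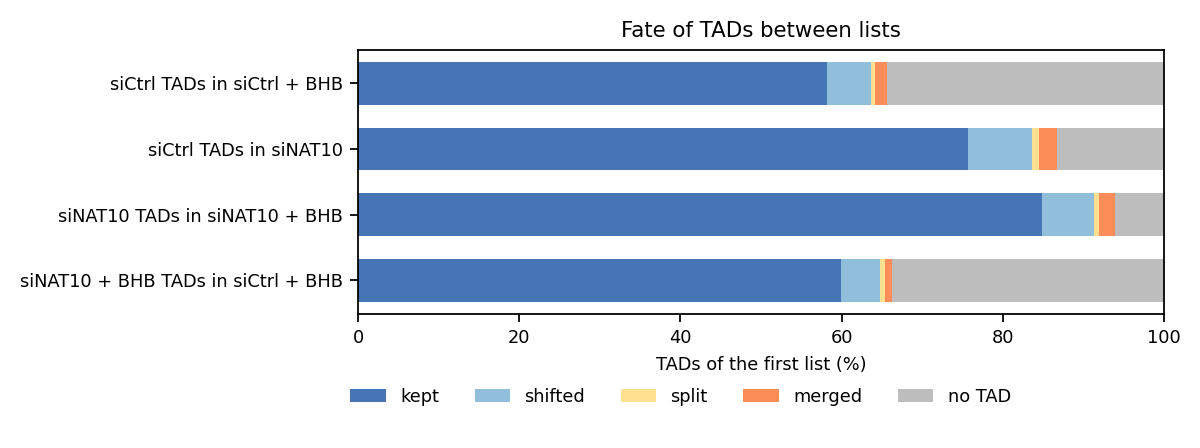
Fate of the TADs of one list in another, as a percentage of the TADs of the first list (horizontal axis), for 4 ordered pairs of lists (bars). In both pairs looked up in BHB-treated control cells the grey part, TADs with under 50% of their length covered by TADs of the other list, takes 34.4% and 33.7%, against 13.2% and 6.06% in the other bars.

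The longest runs of consecutive control boundaries without a match in BHB-treated control cells lay on chromosomes 1, 7, X, 11 and 13. On chromosome 1, from 185280001 to 200520000, a span of 15.24 Mb held 10 TADs and 18 boundaries in control cells and neither a TAD nor a boundary after BHB. Knockdown cells had 12 boundaries there, and BHB-treated knockdown cells had 11. On chromosome 7, from 62960001 to 72560000, TADs covered 24.6% of the span in control cells, 2.9% after BHB, 16.7% in knockdown cells and 25% in BHB-treated knockdown cells. On chromosome X, from 88600001 to 92080000, control cells had 14 boundaries, BHB-treated control cells 0, knockdown cells 3 and BHB-treated knockdown cells 7. On chromosome 11, from 78520001 to 85560000, control cells had 7 TADs, BHB-treated control cells 0, knockdown cells 9 and BHB-treated knockdown cells 10. On chromosome 13, from 72480001 to 77600000, TADs covered 45.3% of the span in control cells, 0 with BHB, 31.2% in knockdown cells and 46.9% in BHB-treated knockdown cells. These regions were selected as runs of control boundaries without a match in the treated control list, so the missing matches follow from that choice. The knockdown lists did not enter the choice, but a list picked for missing boundaries will tend to lie below any other list there. The difference between the treated control list and the knockdown lists in these regions is therefore in part fixed by the choice. The genes in them were not analysed here, and whether the regions lie over gaps or repeated sequence in hg19 was not checked.

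**Figure D3:**
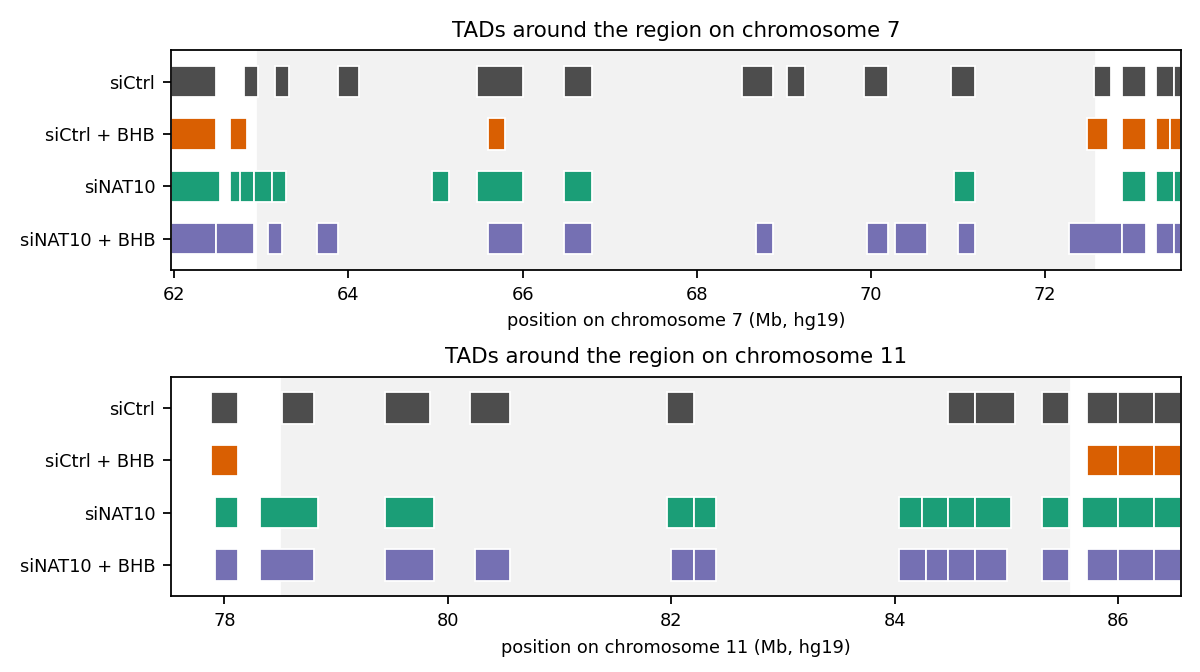
TADs (boxes) of the 4 lists (rows) around a region of chromosome 7 and a region of chromosome 11, drawn to scale along hg19 positions in Mb, with the region shaded. In the shaded part of chromosome 11 the BHB-treated control row is empty, and the other rows hold 7, 9 and 10 TADs.

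The next comparison set NAT10-knockdown cells against control cells, both without BHB. The knockdown list had 3.9% fewer TADs, with fewer on 17 chromosomes, equal numbers on 2 and more on 4. Chromosome 22 had 85 TADs against 101 in control cells, and chromosome 11 had 268 against 259. Of the control boundaries, 85.6% (84.9 to 86.4) were found in knockdown cells, against 31.3% under random shifts, and 1133 were not. In the other direction 87.9% (87.2 to 88.6) of the 7658 knockdown boundaries were found in control cells, and 924 were not. At exactly the same position, 2179 control boundaries were not found in knockdown cells and 1944 in the other direction. Among control TADs, 4111 (75.7%) kept both edges, 717 (13.2%) had no TAD in the knockdown list, 126 were merged and 47 were split. Without replicate lists, it could not be tested whether differences of this size exceed those between libraries of one condition.

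Chromosome X from 88840001 to 91800000, inside the longer stretch named for BHB, held the longest run of control boundaries without a match in knockdown cells, with 9. It was followed by chromosome 5 from 117640001 to 121280000, where control cells had 4 TADs and 8 boundaries, knockdown cells and BHB-treated control cells had 0, and BHB-treated knockdown cells had 2 TADs. On chromosome 9, between 43000001 and 45520000, TADs covered 68.3% of the span in control cells, 58.7% with BHB, 7.9% in knockdown cells and 14.3% in BHB-treated knockdown cells. A second span of chromosome 9, from 81400001 to 85920000, had 7 boundaries in control cells and 1 in knockdown cells. On chromosome 2, from 150600001 to 151920000, TADs covered 87.9% in control cells, 0 in knockdown cells and in BHB-treated control cells, and 54.5% in BHB-treated knockdown cells. These regions were selected for control boundaries without a match in the knockdown list, so its low values there are in part fixed by the choice. Whether they lie over gaps or repeated sequence in hg19, where a difference may not reflect folding, was not checked.

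BHB-treated and untreated cells were then compared within the NAT10 knockdown. Here the BHB-treated list had 3.4% more TADs than the untreated one, with more on 20 chromosomes and fewer on chromosomes 15, 16 and 17. Chromosome 13 had 146 TADs with BHB and 127 without, and chromosome 16 had 156 with BHB and 163 without. TADs covered 84.1 Mb more with BHB, of which a single TAD of 21.4 Mb on chromosome 1, from 121320001 to 142720000, is a part. Leaving out TADs over 3 Mb, the difference was 61.6 Mb. Of the 7658 knockdown boundaries, 91.2% (90.6 to 91.9) were found after BHB, against 31.7% under random shifts. In the other direction 89.6% (88.9 to 90.3) were found. Boundaries without a match numbered 671 and 811 in these directions, and 1449 and 1616 when the same position was required. Both edges were kept for 4428 (84.9%) of the knockdown TADs, and 316 (6.06%) had no TAD in the BHB-treated list.

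The longest runs of knockdown boundaries without a match after BHB held at most 6 boundaries, and runs in the other direction were not searched. Chromosome 1 from 147560001 to 149440000 had 6 such boundaries, and the covered share there was 40.4% in knockdown cells and 70.2% after BHB. On chromosome 12, from 8680001 to 9600000, knockdown cells had 2 TADs and BHB-treated knockdown cells 0. On chromosome 10, from 122360001 to 123520000, TADs covered 55.2% before BHB and 27.6% after. The remaining regions lay on chromosome 16, from 28320001 to 29440000 and from 21480001 to 22520000, each with 4 unmatched boundaries. In all of these regions the missing matches after BHB follow from the choice. Gaps and repeated sequence in hg19 were not checked here either.

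The last pair set BHB-treated knockdown cells against BHB-treated control cells. The knockdown list had 47.5% more TADs, with more on all 23 chromosomes. In percent, the difference ranged from 26.4% on chromosome 19, with 158 against 125, to 89.6% on chromosome 13, with 146 against 77. TADs covered 518.3 Mb more of the genome. Of the boundaries in BHB-treated control cells, 93.9% (93.3 to 94.5) were found in BHB-treated knockdown cells, and 347 were not. With the knockdown list thinned at random to 3655 TADs, 1474 (25.7%) were not found, a rise that follows from the removal of TADs itself. At exactly the same position in the full list, 1008 were not found. Of the boundaries in BHB-treated knockdown cells, 70.2% (69.2 to 71.2) were found in BHB-treated control cells, against 23.6% under random shifts, and 2329 were not. Among TADs of BHB-treated knockdown cells, 1817 (33.7%) had no TAD in BHB-treated control cells. This comparison and the first share the BHB-treated control list, so they are not independent measurements of it.

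Runs of BHB-treated control boundaries missing from BHB-treated knockdown cells reached at most 4. Runs in the other direction, where 2329 boundaries had no match, were not searched. The runs of 4 lay on chromosome 9 from 40600001 to 43520000, on chromosome 1 from 147560001 to 148640000, on chromosome 5 from 69880001 to 70320000 and on chromosome X from 120080001 to 120240000. A run of 3 lay on chromosome 7 from 65800001 to 72720000, where BHB-treated control cells had 1 TAD and BHB-treated knockdown cells had 7. On chromosome 5 the span had 2 TADs in BHB-treated control cells and 2 in knockdown cells, and 0 in the other lists. The missing matches in BHB-treated knockdown cells follow from the choice of these regions, and gaps or repeated sequence in hg19 were again not checked.

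**Figure D4:**
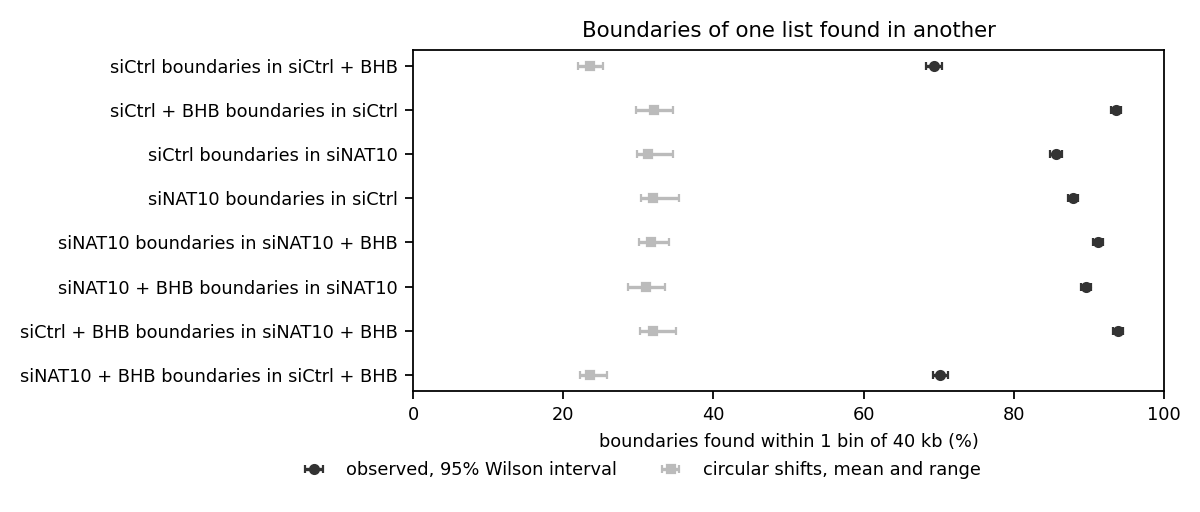
Percentage of the boundaries of one list (rows) found within 1 bin of 40 kb in another list (horizontal axis). Dark points are the observed shares with 95% Wilson intervals, and grey squares are means over 200 circular shifts with their range. Shares looked up in the BHB-treated control list are 69.4% and 70.2%, and the other 6 lie between 85.6% and 93.9%.

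The design also asks whether the boundaries missing after BHB in control cells were present when NAT10 had been knocked down. Control and knockdown cells shared 6760 control boundaries, of which 94.2% (93.6 to 94.7) were present in BHB-treated knockdown cells. Of the 6760, 1481 were missing in BHB-treated control cells. Among the 1481, 1195 were present in BHB-treated knockdown cells, a share of 80.7% (78.6 to 82.6), which is below that over all 6760. Of the 934 missing boundaries that untreated knockdown cells also lacked, 247 were present there, 26.4% (23.7 to 29.4), against 101 of the 199 that untreated knockdown cells lacked and BHB-treated control cells kept, 50.8% (43.9 to 57.6). Over all 2415 control boundaries missing after BHB, the share was 59.7% (57.7 to 61.6), or 1442 boundaries. Among the 5279 shared boundaries that BHB-treated control cells kept, the share present in BHB-treated knockdown cells was 98.0% (97.6 to 98.3). When boundaries of all lists were joined into 8970 sites, 5092 sites (56.8%) occurred in every list. Another 1181 sites (13.2%) were missing from BHB-treated control cells alone, compared with 154 missing from control cells alone, 91 from BHB-treated knockdown cells alone and 79 from knockdown cells alone. With 1 list per condition there was no test of an interaction between BHB and the knockdown. The boundaries were picked as missing from the short list, and a list short for technical reasons would also give a high share. These shares therefore do not tell whether the loss with BHB needs NAT10.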

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

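The test on bin and minimum TAD size, the setting of the loss of weak boundaries beside that in another list, the interval and direction used for loss near chromosome ends, and the count of adjoining pairs, were chosen only after the result was seen. BHB went with opposite differences in control and in NAT10-knockdown cells, which is what drew attention here. The number of TADs with BHB minus without was -1774 in control cells and 176 in knockdown cells. The number of boundaries differed by -2161 in control cells and by 167 in knockdown cells. The genome covered by TADs differed by -464.4 Mb in control cells and by 84.1 Mb in knockdown cells. Stretches of over 1 Mb without a TAD differed by 163 in control cells and by -9 in knockdown cells. Each of these is a difference between 2 lists, and the difference between the differences was not tested. The flag rested on the sign alone. The 176 TADs in knockdown cells were a difference of 3.4%, smaller in size than the -214 TADs (-3.9%) of untreated knockdown against control cells. Whether TAD number rises with BHB in knockdown cells therefore cannot be told.

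The lower number of TADs in BHB-treated control cells has a biological explanation in the design, a response to BHB that needs NAT10, and technical ones that concern this single list. Another bin or minimum size is argued against: all 4 lists had a bin of 40 kb and a smallest TAD of 120 kb, and over TADs of at least 200 kb the ratio to control cells was still 0.69. A noisier map cannot be told apart from a response to BHB: over 4795 sites where each list had exactly 1 boundary and all lay within 1 bin, the pairs with the BHB-treated control list were in the same bin 88.7% of the time and the other pairs 88.4%, a difference of 0.27 percentage points (bootstrap interval -0.35 to 0.88), but these are boundaries that the treated list retained, and noise that removed boundaries would not show there. A list with lower sensitivity for weak boundaries, as from fewer contacts, stays open too. Control boundaries absent from knockdown cells were lost more often than those present there, 82.4% against 21.9%. This gap of 60.53 points passed the 10 points set beforehand as the prediction of lower sensitivity. By a standard added afterwards, the same gap was 63.49 points for BHB-treated knockdown cells, whose list is not short. That list shares its siRNA with the list used for the split, so the standard is not like for like. Within the knockdown, 30.8% of boundaries absent from control cells and 5.73% of those present there were not found after BHB. The gap therefore does not separate the explanations. The depth of the maps, or lists per replicate, would be needed to decide.

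Among control TADs, being lost with BHB was tied to size: 46.2% of TADs of at most 200 kb had no TAD in the treated list, against 30.1% of those of 240 or 280 kb and 30.2% of those of 320 kb or more, a difference of 15.97 points between smallest and largest with no gradient above 200 kb, so small size may account for a part of the loss but leaves the loss among larger TADs. Lost TADs also followed each other in list order, where they can lie Mb apart, with runs of 1.71 TADs on average against 1.46 to 1.59 over 1000 random choices on the same chromosomes. TADs with no adjoining TAD were lost more often (42.7%) than those adjoined on both sides (30.7%), so runs may in part reflect stretches with few TADs, but among 3224 adjoining pairs both were lost in 413, against 296 to 368 in random choices that kept the number lost for each chromosome and number of adjoining TADs. Preferential loss near the ends of the span that TADs cover on each chromosome is argued against, but only by a standard added afterwards. The share lost within 10 Mb of such an end was 30.0%, against 35.4% elsewhere. The difference was -5.36 points (Newcombe interval -8.46 to -2.14). By the limits set beforehand, a difference of this size was undecided. Size was tied to loss in knockdown against control cells too, where 20.7% of TADs of at most 200 kb and 9.63% of those of 320 kb or more had no TAD, so this profile is not particular to BHB, and whether it comes from folding or from detection remains open.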

How the results depend on the processing

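The alternatives on coverage limits, joined boundaries, TADs under 200 kb or over 1 Mb and sites at 2 bins were chosen after seeing the data. Of 284 alternative values, 76 equal the main value by construction, since no TAD was nested or under 100 kb and a tolerance of 40 kb is 1 bin, and 10 at 100 kb repeat those at 2 bins. Of the other 198, 176 stayed within their limits (a factor of 1.5 for counts and differences, the interval of the main value for sizes and shares), 22 moved and 0 reversed. The numbers of TADs and the Mb covered, with their differences between lists, stayed within limits under every size filter and chromosome choice run. For the totals and the large differences this says little, since the filters took out few TADs. The lowest number left in control cells was 4976 of 5429, far from a factor of 1.5. Small differences could move: without TADs under 200 kb, knockdown minus control was -143 TADs in place of -214. Means in place of medians gave 288.9 kb in control, 300.1 kb in BHB-treated control, 294.6 kb in knockdown and 300.7 kb in BHB-treated knockdown cells. With a match required at the same position, boundaries not found numbered 1031 of BHB-treated control in control, 2179 of control in knockdown, 1944 of knockdown in control, 1449 of knockdown in BHB-treated knockdown, 1616 in the reverse direction and 1008 of BHB-treated control in BHB-treated knockdown cells. Among boundaries shared by control and untreated knockdown cells, the share of those missing after BHB that BHB-treated knockdown cells had was then 73.6% in place of 80.7%, and that of the kept ones 94.7% in place of 98.0%. The latter was 98.4% at 2 bins, which is the same setting as 100 kb here. Away from stretches of over 1 Mb without TADs, where fewer boundaries remain, those not found numbered 192 (6.06%) of BHB-treated control in control, 613 (10.9%) of knockdown in control, 519 (8.9%) of BHB-treated knockdown in knockdown, 194 (6.13%) of BHB-treated control in BHB-treated knockdown and 1491 (25.6%) in the reverse direction. With the longer list thinned at random to equal length, 1508 boundaries of BHB-treated control cells were not found in control and 1474 not in BHB-treated knockdown cells. Random removal of TADs takes matches away by itself, so more boundaries not found and fewer kept TADs were fixed in advance. BHB-treated control TADs with both edges kept then numbered 2125 (58.1%) in control and 2187 (59.8%) in BHB-treated knockdown cells, in place of 86.4% and 88.3%, a factor just under 1.5. With TADs under 75% covered counted as lost, BHB-treated control cells had 196 TADs without one in control and 137 without one in BHB-treated knockdown cells. Where no cause is given by the alternative's construction, the cause was not tested. No paired analysis was possible because the lists carry no replicates; leaving out a replicate was not possible for the same reason. The alternatives on gene lists and on sequence at boundaries were not run. Unknown depth limits every comparison.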

Other observations

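TADs over 3 Mb were few, 11 in control, 11 in BHB-treated control, 13 in knockdown and 14 in BHB-treated knockdown cells. On 9 chromosomes, 4, 6, 7, 8, 11, 12, 16, 18 and X, all 4 lists had one. The one on chromosome 16 ran from 34680001 to 46680000 in control cells, 12 Mb, and measured 12.04 Mb, 11.92 Mb and 11.88 Mb in the other lists. The largest, 21.4 Mb on chromosome 1 from 121320001 to 142720000, occurred in BHB-treated knockdown cells and in no other list. Large gaps in the hg19 sequence lie around the centromeres of chromosomes 1 and 16, where no reads map, as background knowledge not checked here. On chromosome 5 a TAD of over 3 Mb, from 46240001 to 49640000, occurred in both lists without BHB and in neither list with BHB. On chromosome 2 a TAD of over 3 Mb, from 92000001 to 95520000 in knockdown cells, occurred in both knockdown lists and in neither control list. Both were singled out after their values were seen. Whether they, the TAD of 3.68 Mb on chromosome 21 or the other TADs of over 3 Mb also lie over sequence gaps was not checked. A difference between lists in such a TAD may therefore not reflect folding.

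Some boundary sites were shared by the lists of one siRNA alone. Of the 8970 sites, 422 occurred in both knockdown lists and in neither control list, and 71 in both control lists and in neither knockdown list. The untreated pair alone shared 248 sites, and the BHB-treated pair alone shared 34. Of the pairs with neither siRNA nor treatment in common, control and BHB-treated knockdown cells alone shared 219, and BHB-treated control and untreated knockdown cells alone shared 39. Sites found in a single list numbered 637 for control, 404 for BHB-treated knockdown, 210 for knockdown and 89 for BHB-treated control cells. Identical TADs, with the same start and end, numbered 3578 between the knockdown lists, 3070 between the untreated lists, 2488 between the BHB-treated lists and 2444 between the control lists. They numbered 3021 between control and BHB-treated knockdown cells and 2495 between BHB-treated control and untreated knockdown cells. The short list of BHB-treated control cells lowers every count that includes it. It also raises counts of sites that must be absent from it, here the 422, 248 and 219 sites and the single-list counts of 637, 404 and 210. The contrast of 422 with 71 is therefore skewed on both sides by that list.

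Control TADs with no adjoining TAD lacked a TAD in BHB-treated control cells in 42.7% of cases (39.6 to 45.8), against 30.7% (28.7 to 32.8) of those adjoined on both sides. The corresponding shares in untreated knockdown cells were 18.4% (16.1 to 20.9) and 10.8% (9.49 to 12.2).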
